A study of Tetranychus urticae with 8 samples.

How the data were processed

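Total RNA of about 100 adult females per extract was labelled from 100 ng per dye with spike-in RNA and hybridised to 2-colour arrays, per the labels' protocols. The labels give 8 arrays in 2 groups of 4 biological replicates, Col-0 (Cy5) against bean (Cy3) and qKo (Cy5) against Col-0 (Cy3), with the same dye orientation on every array. The scanner files hold spot intensities from Agilent Feature Extraction, version 10.7.1.1 per the file headers and 10.5 per the submitters' processing notes, with median foreground and median local background signals, Agilent's processed signals, its log10 ratio and quality flags. The deposited value table holds log2 ratios of Cy5 over Cy3. On each of the 8 arrays it equalled, within 0.01 for 100% of spots, the log2 ratio that normexp background correction (offset 50) and loess on the median signals give, and its columns' medians lay between -0.0024 and 0.0034. The submitters' notes name limma.

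Here the scanner intensities were read with limma 3.58.1 in R 4.3.3. The design chosen before the data were examined named mean spot signals; the files used here give medians, so median signals were used. Background was corrected with normexp (offset 50), and each array was normalised by loess with control spots at weight 0. Control spots and spots marked as outliers were then left out, spots of one probe were averaged, and a gene's value was the mean over its kept probes. A probe was kept where at least 1 channel was well above background on at least 3 of 4 arrays of at least 1 comparison, which kept 42320 of 56184 probes and 15635 of 18774 identifiers. No sample column outside the series was used.

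One limma fit with a mean per comparison (8 arrays, 6 residual degrees of freedom) tested each mean ratio against 0 and the difference between the means, two-sided, with Benjamini-Hochberg adjustment at 0.05. The p-values and SEs measure a spread between replicates that is pooled over both comparisons and moderated across genes. They do not measure the spread of the 4 replicates of 1 comparison alone. Dyes were not swapped, so gene-specific dye effects stay in both ratios; an effect shared by all arrays cancels in the difference only. The fit was tested on simulated ratios of 15635 genes with 200 changed genes and shared Cy3 noise. At a log2 change of 1 it recovered 97.3% for Col-0 against bean, 94.7% for qKo against Col-0 and 91% for the difference, and at 0.5 it recovered 83.3%, 82.7% and 61.7%. False calls were 4.58%, 6.01% and 0.218% of the calls.

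Of the identifiers on the array, 376 carry a gene name and 370 of these were tested; the reference table of the assembly NJAU_TeUrti_SD_1.0 matched none of the identifiers, so gene names are those of the files. Named and unnamed identifiers of one number did not behave as one gene (r = 0.16 of the log2 ratio over 258 pairs), so they were kept apart. Whether a gene is present under both kinds of identifier was not tested. The gene lists fixed before the data were examined rely on gene descriptions, which the files used here do not pair with the identifiers. They were replaced by 21 lists built from the names after the identifiers had been seen and before any gene's ratio was looked at. List members are identifiers. Some share a name (CYP385B1), differ from another only by a suffix (CYP385C3 and CYP385C3v2) or are named as a pseudogene (CYP-pseudogene). Each was counted as a member. Lists with at least 5 tested members (19) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. With the estimated correlation 0 of the 38 list tests of the 2 comparisons passed adjustment (7 passed unadjusted), against 19 with the preset one, and fry, which asks whether a list's genes move one way on balance, passed 21.

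Named genes are the 10 with the largest rise and the 10 with the largest fall per comparison among genes past the threshold with the same sign on 4 of 4 arrays, and up to 4 such members of each list with the largest change, a number raised from 1 when the lists were replaced. At most 2 unnamed identifiers per direction and comparison are printed. Other genes named in the text, among them TuGSTm05 and TuGSTm11, were chosen after their values were seen. Correlations between the comparisons were set against simulations with shared and unshared RNA.

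The numbers of the replicates were checked for pairing between the comparisons by correlating the deviations of the ratios from their group means. One of the 4 pairs was under 0.1, so the numbers were not taken to pair the arrays, although same-numbered Cy3 channels deviated together. If the numbers do pair the arrays, the test of the difference between the comparisons is too strict, since it leaves the shared spread in. The counts with a replicate block had been seen before this was decided. Alternatives changed the background correction, normalisation, source of values, filter on dim probes, probe summary, arrays in the fit, array weights, fold threshold, replicate block, slide row and list correlation, and left out each array in turn. The count over unnamed identifiers alone was added after seeing the data.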

Results

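Gene expression was measured in adult females of the two-spotted spider mite, *Tetranychus urticae*, a plant-feeding arachnid, on 2-colour Agilent oligonucleotide arrays after 24 h on a host plant. Bean is the ancestral host of the strain. Col-0 is the reference accession of *Arabidopsis thaliana*, and qKo is an Arabidopsis line mutated in MYB28, MYB29, CYP79B2 and CYP79B3, genes of glucosinolate synthesis (glucosinolates are sulphur-containing defence compounds of the cabbage order). By the labels, 4 arrays set RNA of Col-0-fed mites (Cy5) against RNA of bean-fed mites (Cy3), and 4 arrays set RNA of qKo-fed mites (Cy5) against RNA of Col-0-fed mites (Cy3). The comparisons ask how mites respond to a new host and how that response differs on the mutant line qKo. Arrays with another line, atr1D, were not analysed here. Between 72.2% and 78.5% of the 61657 gene spots were well above background per channel and array, no gene spot was saturated, and 15635 genes were tested. The number of arrays, 4 per comparison, limits the precision.

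The Cy3 channels of the 2 sets of arrays matched against the labels, and which RNA each dye held was not settled. By the labels the Cy3 channel held bean RNA in one set of arrays and Col-0 RNA in the other, yet for all 116 genes that differed at least 4-fold on the Col-0 against bean arrays, the Cy3 level on the qKo arrays lay closer to the Cy3 level of the Col-0 against bean arrays than to their Cy5 level. The root mean square distance was 0.16 to Cy3 and 3.06 to Cy5 on the log2 scale. Same-numbered Cy3 channels of the 2 sets correlated across genes at r = 0.9968 to 0.9993, against 0.972 to 0.979 for qKo-array Cy3 with Cy5 of the Col-0 against bean arrays and 0.990 to 0.994 for qKo-array Cy5 with their Cy3. Same-numbered Cy5 channels of the 2 sets correlated at r = 0.979 to 0.984. Both qKo-array channels thus lay closer to Cy3 of the Col-0 against bean arrays than to Cy5 there. The deviations of same-numbered Cy3 channels from their group means correlated at r = 0.683 to 0.806, against -0.176 to 0.394 for Cy3 with Cy5, -0.249 to 0.614 for Cy5 with Cy5 and -0.052 to 0.252 for Cy5 with Cy3. Values of the Col-0 against bean arrays are therefore given by dye, with the label beside it, and every direction in both comparisons holds only as labelled.

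**Figure D1:**
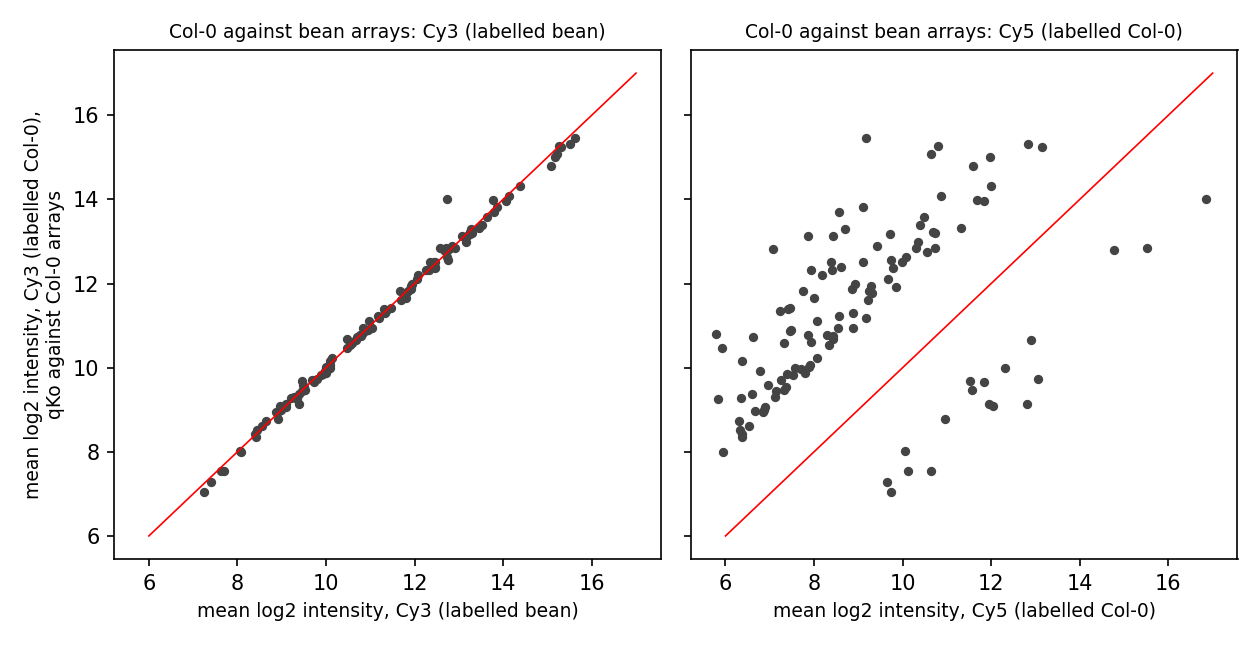
Mean log2 intensity of the 116 genes with an at least 4-fold ratio on the Col-0 against bean arrays. The Cy3 channel of the qKo against Col-0 arrays (vertical axis, labelled Col-0) is plotted against the Cy3 channel (left, labelled bean) and the Cy5 channel (right, labelled Col-0) of the Col-0 against bean arrays; each point is a gene, a mean over 4 arrays per channel, and the red line marks equal intensity, which the points follow on the left only.

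On the Col-0 against bean arrays, most cytochromes P450 and glutathione S-transferases were brighter in Cy3, the channel labelled bean. The glutathione S-transferase TuGSTm03 was 7.56-fold brighter in Cy3 (log2 2.92 ± 0.10, SE, n = 4), the carboxyl/cholinesterases TuCCE-29 and CCEinc-06 were brighter in Cy3 by log2 2.66 ± 0.13 and 2.58 ± 0.13 (SE, n = 4), and the cytochromes P450 CYP389A1, CYP392D8 and CYP392A3 by log2 2.46 ± 0.18, 2.39 ± 0.20 and 2.34 ± 0.08 (SE, n = 4). All 6 had the same sign on 4 of 4 arrays, with limma adjusted p between 9.54e-08 and 1.44e-05. Each SE printed with a log2 ratio is limma's moderated value from the fit to all 8 arrays, and n counts the arrays in the mean. The spread of those 4 arrays alone can be larger (CYP389A1) or smaller (neverland). Fewer named genes were brighter in Cy5, labelled Col-0, among them the P450s CYP381A2 at log2 1.70 ± 0.07 and CYP385A1 at log2 1.65 ± 0.07 (SE, n = 4). Over all genes, 7048 of 15635 differed between the dyes at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg), 3587 brighter in Cy3 and 3461 brighter in Cy5. Of these, 330 were at least 2-fold brighter in Cy3 and 152 in Cy5, and 98 and 18 were so at least 4-fold. With the labels as given, the 3587 genes were lower in Col-0-fed than in bean-fed mites, and with the 2 labels exchanged they were higher.

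Cytochromes P450 are monooxygenases that oxidise plant toxins and pesticides, among other substrates. Of 104 tested, 67 were brighter in Cy3, 16 were brighter in Cy5, and 21 did not pass the test. The difference from other genes had a camera adjusted p of 1.66e-09, and an adjusted p of 0.348 with an estimated correlation. The family CYP392 gave 36 of 43 members brighter in Cy3 and 2 brighter in Cy5, with a median log2 ratio of Cy3 over Cy5 of 0.76 (camera adjusted p = 2.33e-14, and adjusted p = 0.348 with an estimated correlation). CYP392D6 reached log2 2.17 ± 0.05 and CYP392A1 log2 1.79 ± 0.09 (SE, n = 4). In the family CYP385, 9 of 10 members were brighter in Cy3, such as CYP385C4 at log2 1.61 ± 0.09 (SE, n = 4), while CYP385A1 was brighter in Cy5. Its camera adjusted p was 2.46e-05, and its adjusted p was 0.348 with an estimated correlation. Of 14 CYP389 genes, 5 were brighter in Cy3 and 3 in Cy5, and the family as a whole did not pass (camera adjusted p = 0.394). Adjusted over the list alone, 70 of the 104 P450 genes were brighter in Cy3 and 16 in Cy5.

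Glutathione S-transferases, which join glutathione to reactive compounds, gave 23 of 37 members brighter in Cy3 and 5 brighter in Cy5 (camera adjusted p = 9.69e-07, and adjusted p = 0.348 with an estimated correlation). The mu class held 9 of 12 members brighter in Cy3, with TuGSTm02 at log2 1.52 ± 0.07 (SE, n = 4), and had a camera adjusted p of 0.000295 and an adjusted p of 0.348 with an estimated correlation. The delta class held 10 of 16, with TuGSTd02 at log2 1.23 ± 0.08 (SE, n = 4). The delta class had a camera adjusted p of 0.000295, an adjusted p of 0.44 with an estimated correlation, and an adjusted p of 0.0551 with median centring in place of loess. Carboxyl/cholinesterases, a family of ester-cleaving enzymes and their relatives, went both ways. Of 87 tested, 36 were brighter in Cy3 and 24 in Cy5, and the family did not pass as a whole (camera adjusted p = 0.215). ABC transporters, which pump substrates across membranes, also went both ways, with 36 of 117 brighter in Cy3 and 28 in Cy5 (camera adjusted p = 0.777).

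Genes of ecdysteroid synthesis, the pathway of the moulting hormone, were the list that passed camera with brighter Cy5 signals. Of 5 tested, 3 passed, and these were neverland, an enzyme of the first step from cholesterol, at log2 0.76 ± 0.04, CYP307A1 at log2 0.39 ± 0.04 and CYP315A1 at log2 0.32 ± 0.07 (SE, n = 4). The camera adjusted p was 0.0126, and the adjusted p was 0.348 with an estimated correlation. Among genes without a name in the files, tetur09g06670 and tetur20g00200 were brightest in Cy5 relative to Cy3, at log2 4.13 ± 0.13 and 3.40 ± 0.12 (SE, n = 4). In the other direction, tetur05g01720 and tetur06g03550 were brighter in Cy3 by log2 6.44 ± 0.18 and 5.72 ± 0.24 (SE, n = 4). With median centring in place of loess, the median ratio of all genes was 0.15 (log2), and the split became 7070 brighter in Cy5 against 3421 brighter in Cy3. Dyes were not swapped on any array, so a gene's own dye effect is part of each ratio.

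**Figure D2:**
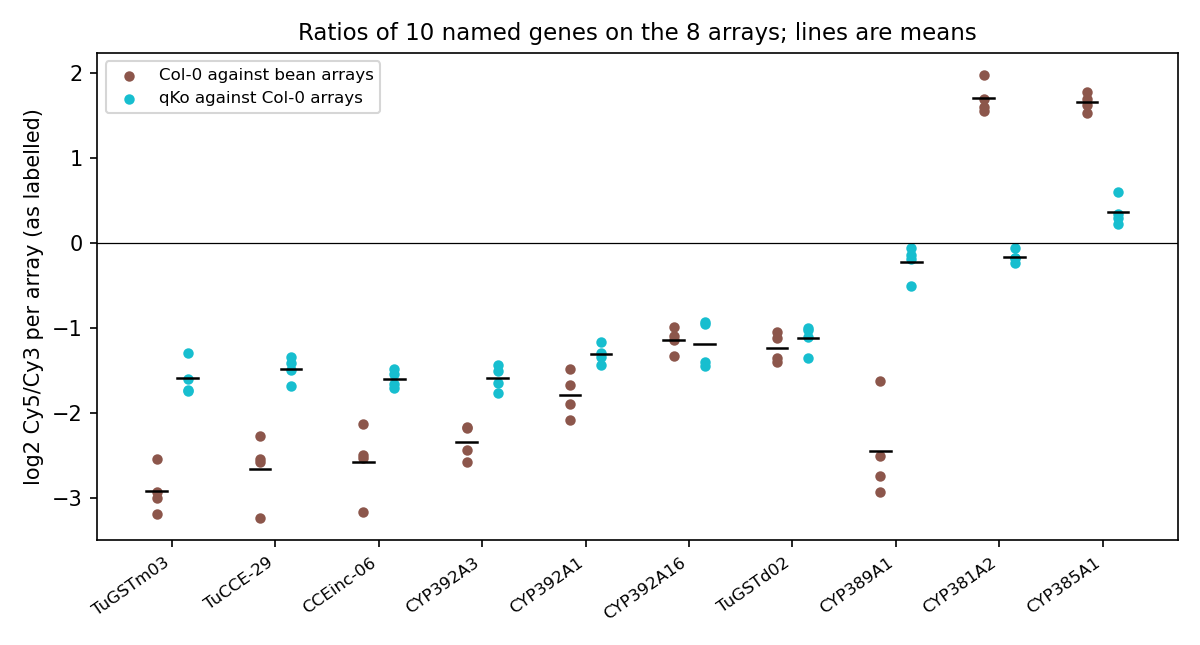
Log2 ratio of Cy5 over Cy3 on each array for 10 named genes; points are arrays (4 per comparison), short lines are means, and the horizontal line marks equal intensity. TuGSTm03, TuCCE-29, CCEinc-06 and CYP392A3 were below 0 on all 8 arrays, while CYP381A2 and CYP385A1 were above 0 on the Col-0 against bean arrays.

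On the qKo against Col-0 arrays, the same families held the named genes that changed, and nearly all of these fell in the RNA labelled qKo. CCEinc-06 fell by 1.60 ± 0.13, TuGSTm03 by 1.60 ± 0.10, CYP392A3 by 1.59 ± 0.08 and TuCCE-29 by 1.49 ± 0.13 on the log2 scale (SE, n = 4), each on 4 of 4 arrays, with limma adjusted p between 2.93e-05 and 0.000343. CYP392A1 fell by 1.31 ± 0.09, CYP392A16 by 1.19 ± 0.10 and TuGSTd02 by 1.12 ± 0.08 (SE, n = 4). Over all genes, 616 changed at an adjusted p under 0.05 (limma, two-sided, Benjamini-Hochberg), of which 408 fell and 208 rose. Of the 408, 42 fell at least 2-fold, while limma called 0 genes that rose at least 2-fold, and 0 also at an unadjusted p under 0.05. Genes with a name made up 76 of the 408 that fell (18.6%) but 2.37% of all tested genes, and the names on this array belong largely to detoxification families.

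Of 104 P450 genes, 34 fell, 2 rose and 68 did not pass (camera adjusted p = 3.69e-20, and adjusted p = 0.11 with an estimated correlation). The 2 that rose were CYP385A1 and an identifier named CYP-pseudogene. CYP392 accounted for 23 of the 34, out of 43 tested, with camera adjusted p = 2.86e-26 and adjusted p = 0.0975 with an estimated correlation. All 23 were also brighter in Cy3 on the Col-0 against bean arrays, as were 36 of the 43 tested. If one RNA was in Cy3 on both sets of arrays, the 2 ratios share it and are not independent observations. Of 37 glutathione S-transferases, 22 fell and the other 15 did not pass (camera adjusted p = 5.11e-21, and adjusted p = 0.0975 with an estimated correlation). They included 11 of 16 of the delta class and 9 of 12 of the mu class, for example TuGSTd07, which fell by 0.95 ± 0.09, and TuGSTm02, which fell by 0.83 ± 0.07 (SE, n = 4). Of 87 carboxyl/cholinesterases, 17 fell and 1 rose, with camera adjusted p = 6.23e-08 and adjusted p = 0.14 with an estimated correlation. CCEinc-01 fell by 1.04 ± 0.07 (SE, n = 4), and the member that rose was TuCCE-33, by 0.54 ± 0.08 (SE, n = 4). Of 117 ABC transporters only TuABCC-21, TuABCC-22 and TuABCC-30 passed, by falling. The family had a median of -0.07 (log2), camera adjusted p = 0.000587 and adjusted p = 0.494 with an estimated correlation. With median centring its camera adjusted p was 0.132. TuABCC-22 lost its call without replicate 1 or 2 of the qKo arrays (limma adjusted p = 0.0501 and 0.0639), and TuABCC-30 without any 1 of the 4 qKo arrays (0.0709 to 0.174). The 42 members of class C had a median of -0.13 (log2), camera adjusted p = 9.83e-08 and adjusted p = 0.328 with an estimated correlation, and with median centring their median lay at -0.08 relative to the median of all genes (camera adjusted p = 0.0368). Adjusted over the list alone, 51 P450 genes and 26 glutathione S-transferases fell.

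Among genes without a name, tetur05g09325 fell by 2.42 ± 0.17 and tetur01g10080 by 1.98 ± 0.22, while tetur11g05840 rose by 0.85 ± 0.11 and tetur27g01640 by 0.79 ± 0.14 (SE, n = 4). The call of tetur27g01640 was lost without replicate 1, 2 or 3 of the qKo arrays, with adjusted p of 0.0701, 0.0739 and 0.0692. The number of changed genes was 346, 180, 222 and 295 without replicates 1 to 4 of the qKo arrays in turn, and 382 without replicate 1 of the Col-0 against bean arrays, which share the estimate of the spread. With median centring in place of loess 2504 genes rose and 762 fell, with the brightest probe per gene 643 rose and 596 fell, with only the 4 arrays of the comparison 74 rose and 393 fell, and without replicate 2 of the qKo arrays 19 rose and 161 fell.

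**Figure D3:**
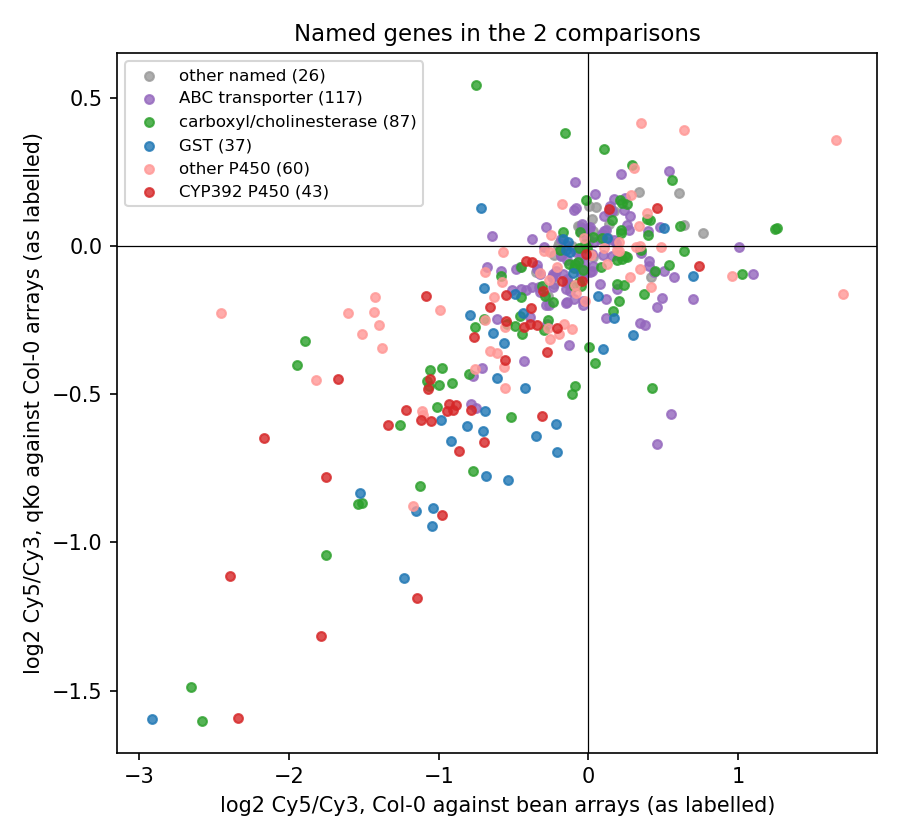
Log2 ratio of Cy5 over Cy3 of the named genes on the Col-0 against bean arrays (horizontal axis) and on the qKo against Col-0 arrays (vertical axis), each a mean over 4 arrays and coloured by family, with the number of genes in the legend. Most CYP392 genes and glutathione S-transferases lie in the lower left, and TuGSTm03, TuCCE-29, CCEinc-06 and CYP392A3 lie farthest from 0 there.

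The log2 ratios of the comparisons were set against each other gene by gene. Of the genes called in both, 325 were dimmer in Cy5 in both, against 93.6 for independent lists, and 146 were brighter in Cy5 in both, against 46.04 for independent lists. In 20 simulated sets with shared Cy3 RNA and no effect, limma called 0 genes in both comparisons in either of these directions, and at an unadjusted p under 0.05 a mean of 227.4 genes had the same direction in both, against 2174 observed. With Col-0 against bean calls from 2 replicate numbers and qKo calls from the other 2, 680 calls summed over the 6 splits were dimmer in Cy5 in both, against 196.6 for independent lists, and 262 were brighter in both, against 131.9, but 1 split gave 475 of the 680 and 259 of the 262. With the same 2 numbers in both, the sums were 1276, against 281, and 759, against 193.1, but 1 split gave 816 of the 1276 and 743 of the 759. Independent lists leave out the shared RNA and the simulation leaves out effects, so an excess over either is no measure of a shared effect. The 325 included 33 P450 genes and 17 glutathione S-transferases. Opposite directions were found for 31 genes that were brighter in Cy5 on the Col-0 against bean arrays and fell in qKo, against 90.3 for independent lists, and for 10 genes the other way, against 47.7. Named among these were the mu-class glutathione S-transferases TuGSTm05 and TuGSTm11 and the transporters TuABCC-21, TuABCC-22 and TuABCC-30 in the first group, and TuCCE-33 in the second. In qKo, TuGSTm05 lost its call without replicate 2, 3 or 4 of the qKo arrays (limma adjusted p = 0.0875, 0.0821 and 0.0822), and TuGSTm11 likewise (0.195, 0.125 and 0.115); TuGSTm11 was also not called on the Col-0 against bean arrays without any 1 of those 4 (0.0589 to 0.082), and had the other sign there with its brightest probe (-0.16). TuABCC-21 had log2 ratios of 0.46 ± 0.09 and -0.67 ± 0.09, and TuCCE-33 of -0.75 ± 0.08 and 0.54 ± 0.08 (SE, n = 4).

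Across genes, which are not independent replicates, the ratios correlated at r = 0.51 (Spearman's rho 0.47), with a covariance of 0.0425. Simulated ratios without any effect gave r = 0.50 and a covariance of 0.00448 where the comparisons shared their Cy3 RNA, r = 0.01 where they shared none, and r = -0.50 where Col-0 RNA was Cy5 in one and Cy3 in the other, as labelled. The simulation gave both dyes an equal share of each gene's ratio variance, which fixes these r in advance. Their closeness to the observed r therefore says nothing about its source. When the Col-0 against bean ratio came from 2 replicate numbers and the qKo ratio from the other 2, r was 0.31 to 0.49 over 6 splits, with a mean covariance of 0.0383, and with the same 2 numbers in both it was 0.344 to 0.646, with a mean covariance of 0.0467.

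The ratio differed between the comparisons for 3143 genes (limma, adjusted p under 0.05), 1505 with a higher and 1638 with a lower Cy5 over Cy3 ratio on the Col-0 against bean arrays. CYP389A1 was among them (adjusted p = 0.000293), dimmer in Cy5 on the Col-0 against bean arrays and at -0.23 ± 0.18 (SE, n = 4) on the qKo arrays, where it did not pass (adjusted p = 0.471). CYP392A16 and TuGSTd02 did not differ at this threshold, with adjusted p of 0.871 and 0.532. In the family CYP385 the ratio was lower on the Col-0 against bean arrays for 7 of 10 genes and higher for 1 (camera adjusted p = 0.000686, and adjusted p = 0.825 with an estimated correlation), and in CYP392 it was lower for 16 of 43 and higher for 1 (camera adjusted p = 1.71e-05, and adjusted p = 0.861 with an estimated correlation). Of the mu-class glutathione S-transferases it was lower for 6 of 12 and higher for 2 (camera adjusted p = 0.0343, and adjusted p = 0.881 with an estimated correlation). It was higher on the Col-0 against bean arrays for 3 of 5 ecdysteroid genes and lower for none (camera adjusted p = 0.024, and adjusted p = 0.825 with an estimated correlation), and higher for 13 of 42 ABC class C transporters and lower for 3 (camera adjusted p = 0.0252, and adjusted p = 0.929 with an estimated correlation). With median centring the split of the differing genes was 2237 higher and 1189 lower. With the replicate block 5055 genes differed, 2346 with a higher and 2709 with a lower ratio. Each comparison lay on a slide of its own, so slide and comparison cannot be told apart in this difference. With the labels as given, Col-0 RNA is Cy5 in one ratio and Cy3 in the other, so the difference contrasts no 2 hosts directly. If one RNA was in Cy3 on both sets, the difference instead compares the Cy5 RNAs of the 2 sets.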

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

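The tests of the channel match were chosen after the match was seen. The control spots named DCP, which no comparison uses, were well above background for at least 83.3% of spots in every channel and array, against at most 2.27% of the negative control spots. Of 102 sets of 4 values, from named genes and array summaries, none had an outlying array by Dixon's test. Chance alone would give about 5.1 in independent sets not chosen by their values. The named genes were chosen for passing the threshold with the same sign on 4 of 4 arrays, and all sets share the 8 arrays. The absence of flags therefore does not show that no array was outlying.

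The Cy3 channels of the 2 sets of arrays match although the labels give them different RNA. The qKo-array Cy3 level was closer to the Cy3 than to the Cy5 level of the Col-0 against bean arrays for 100% of the 116 4-fold genes, as one RNA in Cy3 on both slides would give. Red and green columns exchanged in the files of one slide would turn the spike-in ratios, which correlated between slides at r = 0.9989, and a gene's own dye effect would give the 4-fold genes a similar ratio on the qKo arrays, where their median absolute log2 ratio was 0.4516 (log2). A shared array position would bring Cy5 channels together as well. For the genes at least 4-fold brighter in Cy3 on the Col-0 against bean arrays, mean Cy5 there was 8.55 (log2). On the qKo arrays it was 10.89, while mean Cy3 was 11.55 and 11.53 on the 2 sets. For these genes this argues against position as the source of the matching levels. For the same-numbered deviations position stays open, since those of Cy5 correlated at a mean r of 0.0713 but from -0.249 to 0.614. No biological explanation was tested. A candidate explanation is that the labels of one set are wrong: if the Cy3 RNA was Col-0 in both, the only RNA the labels name in both comparisons, then most P450 and glutathione S-transferase genes that passed would be higher on Col-0 than on bean and on qKo; if it was bean in both, the qKo arrays would compare qKo with bean.

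The 8 sign choices of the 4 arrays are too few for a share under 0.05: 1 of 8 gave as many genes as the real choice, which called 7048 for Col-0 against bean and 616 for qKo against Col-0, and the highest other choice called 0 in each (limma; 1800 and 1511 at an unadjusted p under 0.05). For the difference between the comparisons, 1 of the 35 splits of the 8 arrays, the real one, gave as many genes (3143) and the highest other split called 1, so chance can be excluded only if any array can be exchanged with any other. Of the 8 splits that part all 4 same-numbered arrays, whose Cy3 channels deviate together, the highest other called 0 (limma; at most 595 at an unadjusted p under 0.05), and 8 are too few for a share under 0.05.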

How the results depend on the processing

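The count of changed genes for Col-0 against bean stayed within 1.5 times of 7048 under all alternatives but the 2-fold threshold (482). A similar count did not mean the same genes. With median centring 10491 were called, 5305 of them among the 7048. With the brightest probe per gene 6852 were called, 5808 of them among the 7048, and with the deposited values 7044 of the 7048 stayed called. The qKo count of 616 was less stable. It became 3266 with median centring in place of loess, 1239 with the brightest probe per gene, 942 with array weights, 42 with the 2-fold threshold and 3140 with the replicate block (1636 rose and 1504 fell). The count for the difference became 371 with the 2-fold threshold and 5055 with the replicate block. The cause was not tested, apart from the 2-fold threshold, which can only remove calls, and the replicate block. The block takes the spread shared by same-numbered arrays out of the residual, while each comparison's mean still carries it. Its counts for Col-0 against bean and for qKo can therefore be too high. In the difference the shared spread cancels, so this does not apply there. Leaving out 1 array at a time gave 5250 to 7099 genes for Col-0 against bean, 180 to 644 for qKo, 2139 to 2947 for the difference, 17 to 19 list calls and r = 0.45 to 0.55 between the comparisons. The replicate numbers were not taken to pair the arrays, since the ratio deviations of same-numbered arrays correlated at r = 0.349, 0.0755, 0.802 and 0.458, one of them under 0.1; every Cy3 channel of the qKo arrays correlated best with its own number, as a hint from the data. List calls went from 19 to 0 with an estimated correlation (7 at an unadjusted p under 0.05; fry 21). With median centring 10 values that were called with loess or with median centring changed sign, and after the median of all genes was taken off (0.15 for Col-0 against bean, 0.08 for qKo, log2) only the respiratory chain in qKo, TuABCF-01, both subunit genes and PSST of these kept the changed sign. The 10 were, in qKo, the list medians of ABC class C (0.00015), all ABC transporters (0.021) and the respiratory chain (0.23); in Col-0 against bean, TuCCE-52-gli (0.10), TuABCF-01 (0.34), the subunit genes Tetur283g00020 (0.28) and Tetur11g04150 (0.22), PSST (0.27), TuABCB-02 (0.14) and TYKY (0.14). A further 9 list medians, called under neither normalisation, also changed sign, 6 of them also after the median of all genes was taken off. With the brightest probe TuGSTm11 also changed sign in Col-0 against bean (-0.16). Of 134 results for single genes, 28 lost their call under at least 1 alternative. Over unnamed identifiers alone, chosen after seeing the data, 6784, 475 and 2995 genes were called. Signal over background limits the dimmest genes; without the filter 18774 identifiers gave 6963, 653 and 3107 calls.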

Other observations

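The tests on the correlation and on neighbouring genes were chosen after the patterns were seen. Of 7 acaricide target genes, ACCase, an enzyme of fatty acid synthesis, and RyR, the ryanodine receptor, were brighter in Cy5 on the Col-0 against bean arrays at log2 0.61 ± 0.08 and 0.42 ± 0.05 (SE, n = 4), 1 was brighter in Cy3, and none passed on the qKo arrays. Of 19 transporters of ABC class G, 8 were brighter in Cy3 and 2 in Cy5 (camera adjusted p = 0.241), with TuABCG-08, TuABCG-09 and TuABCG-10, whose identifiers lie close together, at log2 0.68, 0.65 and 0.58. None of the 11 class A transporters passed in either comparison.

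Genes at least 4-fold brighter in Cy3 on the Col-0 against bean arrays lay next to each other in identifier order more often than permuted calls did. The 91 such unnamed identifiers formed 21 adjacent pairs, against a mean of 0.528 and at most 6 in 10000 permutations (permutation p = 1e-04, the smallest they can give), and 23 carried the prefix tetur06. The 33 unnamed identifiers that fell at least 2-fold in qKo formed 3 adjacent pairs (permutation p = 1e-04), while the 18 at least 4-fold brighter in Cy5 on the Col-0 against bean arrays formed none (permutation p = 1). For the first 2 sets chance placement is argued against; neighbouring copies of one gene family, changing together or hybridising to each other's probes, may explain the pairs, and the probe sequences were not used here.

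The correlation of the ratios between the comparisons may have several sources. The shared spread of the Cy3 RNA, estimated from same-numbered arrays, accounted for 9.96% of the covariance. Deviations of probes from the mean of their gene, carried to gene means, accounted for 9.59%. Such deviations can hold other differences between probes as well as dye effects of single probes. Neither source explains the covariance as a whole. A dye effect common to all probes of a gene was not tested, since no dyes were swapped. A difference of the Cy3 RNA from both Cy5 RNAs in the expression of these genes stays open and untested.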
